A study of Mus musculus with 24 samples.

How the data were processed

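The series holds bulk RNA-seq of cultured mouse osteoblasts, the cells that make bone matrix. Per the labels' protocols, the cultures came from the pooled calvariae (skull bones) of newborn wild-type (WT) mice or of mice of a high bone mass (HBM) line, with 3 independent pooled cultures per genotype, sampled at the start of osteoblast differentiation (day 0) and after 10, 15 and 21 days. Polyadenylated RNA was sequenced, per the labels. The series title concerns the removal of the C-terminal propeptide from procollagen; the labels do not give the mutation of the HBM line. From general knowledge of this mouse model, and not from the labels, the line carries a change of the collagen I chain gene Col1a1 at the site where that propeptide is removed. The test of genes near Col1a1 assumes this, and no other test rests on it. The labels number the cultures as batches 18, 19 and 21, with each number present once per genotype and day, so that 24 libraries formed 8 groups of 3. The same batch number on different days was read as the same culture sampled again; the labels do not say this outright.

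The deposited table gives counts of reads per gene for each of the 24 libraries, per the file header and the values, which are whole numbers with a different total in each column. Per the submitters' processing notes, the authors used cutadapt 3.4, STAR 2.7.8a and featureCounts from Subread 2.0.1 with the mouse build mm10. The strand setting of the counting and the annotation release are not given in the sources used here. Reads from a gene and from a partner on the opposite strand could therefore not be told apart, and the treatment of reads that match near-identical genes, such as the osteocalcin genes Bglap and Bglap2, is unknown. The table had 54232 rows named by Ensembl gene identifiers. Of these, 54164 matched the GENCODE M21 annotation of mm10, which supplied symbols and coordinates, and 68 did not, with at most 0.00337% of the counts of any library. All 24 columns were used. Column totals ran from 28039095 to 46987734 counts. The counts carry no molecular identifiers, so counting error understates the error between cultures. The error used was the spread between the cultures of a group, pooled over the 8 groups unless a model of fewer groups or summed counts is named. Days of the same culture entered that pooled estimate as separate libraries, although they are not independent.

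Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by the trimmed mean of M values, with factors from 0.866 to 1.11. Genes were kept by edgeR's filter on low counts for the 8 groups, which left 16592 genes. Every p-value for a single gene is from edgeR's quasi-likelihood test unless DESeq2 is named, and every adjusted p is by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. HBM was compared with WT on each day, and each day with the one before within each genotype, in a single model of the 8 groups. The difference averaged over days was tested on counts summed over the 4 days of each culture (18387 genes kept), and a change of the genotype difference with day was tested with 3 degrees of freedom. Log2 values are those of the model. Levels are CPM (counts scaled by the TMM library size) given as mean ± SD of 3 cultures. These choices, the gene lists, the rule for the genes to be named and most of the alternatives were fixed before the data were examined.

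The model without pairing was the one chosen beforehand, with the batch number as a block as its alternative. Deviations from the group means were then compared between libraries. On each day the WT and HBM libraries with the same batch number deviated together, with correlations across genes from 0.542 to 0.815, and in 12 of 12 cases this was the highest correlation with any library of the other genotype, where other numbers reached at most 0.127. The batch tag of the labels and this check mean that the numbers pair the cultures. Blocked values are therefore given beside the results without a block. The block chosen beforehand was 1 batch term for all days. After the data had been seen, a fit with a separate batch term for each day was added, because the day 0 libraries deviated from the later days of the same culture, with correlations between -0.0186 and 0.443, whereas later days correlated at 0.418 to 0.794. The block chosen beforehand called 0 genes between the genotypes on each of the 4 days, so every call of a single gene by pairing on these days rests on the added fit. The added fit is called the paired fit here and is the blocked fit quoted for the genotype differences on single days. For the average over days and for the changes with time the block is the batch and the culture, respectively. The common biological coefficient of variation was 0.327 without a block and 0.131 in the paired fit.

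Of the genes named in the text, 9 were fixed in advance: Col1a1, Col1a2, Bmp1, Pcolce, Alpl, Bglap, Ibsp, Dmp1 and Sost. Beyond these, the rule took, for each comparison, up to 8 genes per direction (6 between days) with the largest log2 change among those past the threshold, at 1 CPM or more in a group (5 between days), changed in the same direction in all 3 batches and carrying an established symbol. It took up to 3 members of each fixed list with the smallest p, the 10 genes with the smallest p for the change with day, and, where no gene passed, the 3 with the smallest p in each direction among genes open to naming, those that meet the same limits on level, direction and symbol. Its use on the calls of the paired fit was decided after the data had been seen. Names from the end of a ranking were left out for length. Exons of the named genes were compared with those of all other annotated genes. For 4 of them, Phospho1, Fosl1, Ankrd37 and Hs3st3a1, at least 20% of the exonic bases overlapped a gene expressed at 10% or more of their level, and their values are uncertain for that reason.

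The 29 gene lists, 18 of pathways and 11 of cell type markers, were tested with camera from limma 3.58.1, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. At least 3 tested members were required, which left 28 lists; the erythroid list had none. Adjustment was over the 28 lists. For members of a list the number past the threshold is given over all genes and adjusted over the list alone. No list that passed had a median or mean of opposite sign to its test.

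The alternatives were the block, DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 12 libraries, models of only the groups compared, voom for the average over days, and leaving out each library in turn. DESeq2's size factors moved the median log2 change of all genes by at most 0.014. The tests were tried on simulated counts with 200 genes changed by known folds. At day 10 the model without pairing recovered 18%, 58% and 88% of genes changed 1.5-fold, 2-fold and 4-fold. The paired fit recovered 56%, 94% and 100%. Recovery depends on the spread assumed, so these rates do not test the pairing. Of unchanged genes, 6 were called without pairing, 9 in the paired fit and 28 in DESeq2. For the average over days 84% of genes changed 2-fold were recovered, and for the change with day 30%. Genes were drawn independently, so deviations that many genes of 1 culture share are left out.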

Results

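Bulk RNA-seq of cultured mouse osteoblasts, the cells that lay down bone matrix, covered 8 groups: WT and HBM cultures at days 0, 10, 15 and 21 of differentiation, with 3 libraries per group and 24 in all. Each library held 28039095 to 46987734 counts. The first principal component took 54.8% of the variance and parted day 0, at -140.8 to -68.73, from the later days, at 14.84 to 68.31. The second took 14.8% and set batch 21, at -60.87 to -34.96, apart from batch 18, at 12.05 to 43.81, and batch 19, at 15.72 to 40.61. The inactive X transcript Xist, a mark of female cells, was at 0 to 0.0328 CPM in all 8 libraries of batch 21. In batch 18 it was at 297 to 322 CPM in WT and 279 to 528 in HBM, with the Y-linked Ddx3y at 21.5 to 32.6 and 12.1 to 18.2 CPM. In batch 19 Xist was at 18.0 to 41.7 CPM in WT and 177 to 246 in HBM, so the sex composition of the pools differed between the genotypes there. In batch 18 Xist overlapped between the genotypes, but Ddx3y was lower in HBM on each day, as were the Y-linked Eif2s3y, Kdm5d and Uty. This points to a smaller share of male cells in the HBM pool of batch 18 too. Only in batch 21 did both pools lack Xist. The WT day 0 library of batch 19 stood apart in the cartilage collagen Col2a1, at 15900 CPM, and in Ddx3y, at 22.2 CPM against 55.6 to 62.8 on the other days of that culture.

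**Figure D1:**
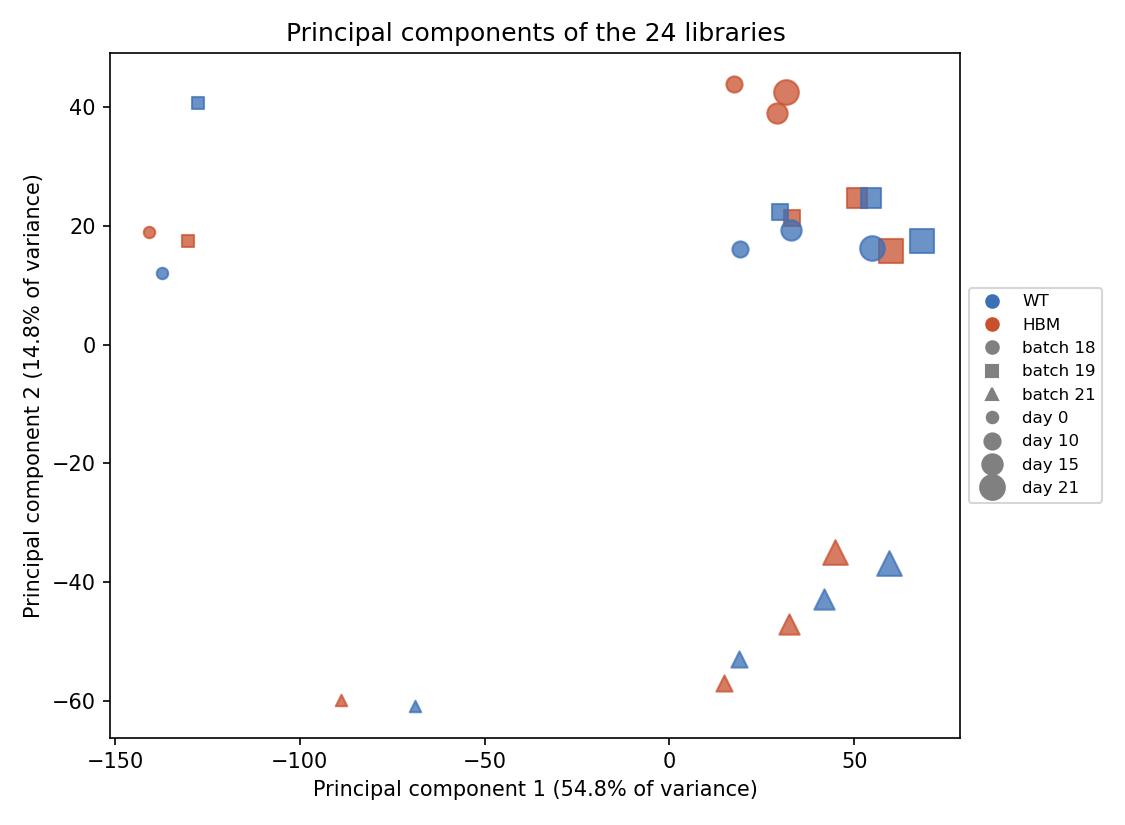
Scores of the 24 libraries on the first and the second principal component (no unit), with genotype, day and batch marked. Day 0 libraries sit at -140.8 to -68.73 on the first component, and the 8 libraries of batch 21 at -60.87 to -34.96 on the second.

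The genes fixed in advance were those of collagen I, of the removal of its C-propeptide and of bone formation. Their levels are given as mean ± SD of 3 cultures. Col1a1 and Col1a2, the 2 chains of collagen I, stood at 24400 ± 7710 and 16000 ± 3690 CPM in WT cultures at day 0 and at 45500 ± 15100 and 41500 ± 15800 at day 21. Bmp1, the protease that removes the C-propeptide of procollagen I, stood at 253 ± 25.7 CPM at day 0 and 358 ± 91.8 at day 21. Its enhancer Pcolce stood at 897 ± 328 and 1360 ± 369 CPM. The bone alkaline phosphatase gene Alpl went from 10.9 ± 15.0 to 266 ± 154 CPM and osteocalcin, Bglap, from 0.133 ± 0.0776 to 421 ± 246. Bone sialoprotein, Ibsp, was at 0.223 ± 0.0762 CPM at day 0 and 964 ± 557 at day 21. The osteocyte genes Dmp1 and Sost, the latter a secreted Wnt inhibitor, were at 0.937 ± 0.516 and 0 CPM at day 0 and at 26.5 ± 3.04 and 21.8 ± 22.3 at day 21.

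In the mm10 build these genes lie as follows. Col1a1 (ENSMUSG00000001506) is at chromosome 11, 94936224 to 94953042, plus strand, and Col1a2 (ENSMUSG00000029661) at chromosome 6, 4504814 to 4541544, plus strand. Bmp1 (ENSMUSG00000022098) is at chromosome 14, 70474558 to 70520234, and Pcolce (ENSMUSG00000029718) at chromosome 5, 137605103 to 137613784, both on the minus strand. Alpl (ENSMUSG00000028766) is at chromosome 4, 137741733 to 137796384, and Bglap (ENSMUSG00000074483) at chromosome 3, 88383501 to 88384464, both minus. Ibsp (ENSMUSG00000029306) and Dmp1 (ENSMUSG00000029307) lie close together on the plus strand of chromosome 5, at 104299171 to 104311469 and at 104202613 to 104214102. Sost (ENSMUSG00000001494) is at chromosome 11, 101962458 to 101967015, minus strand.

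**Figure D2:**
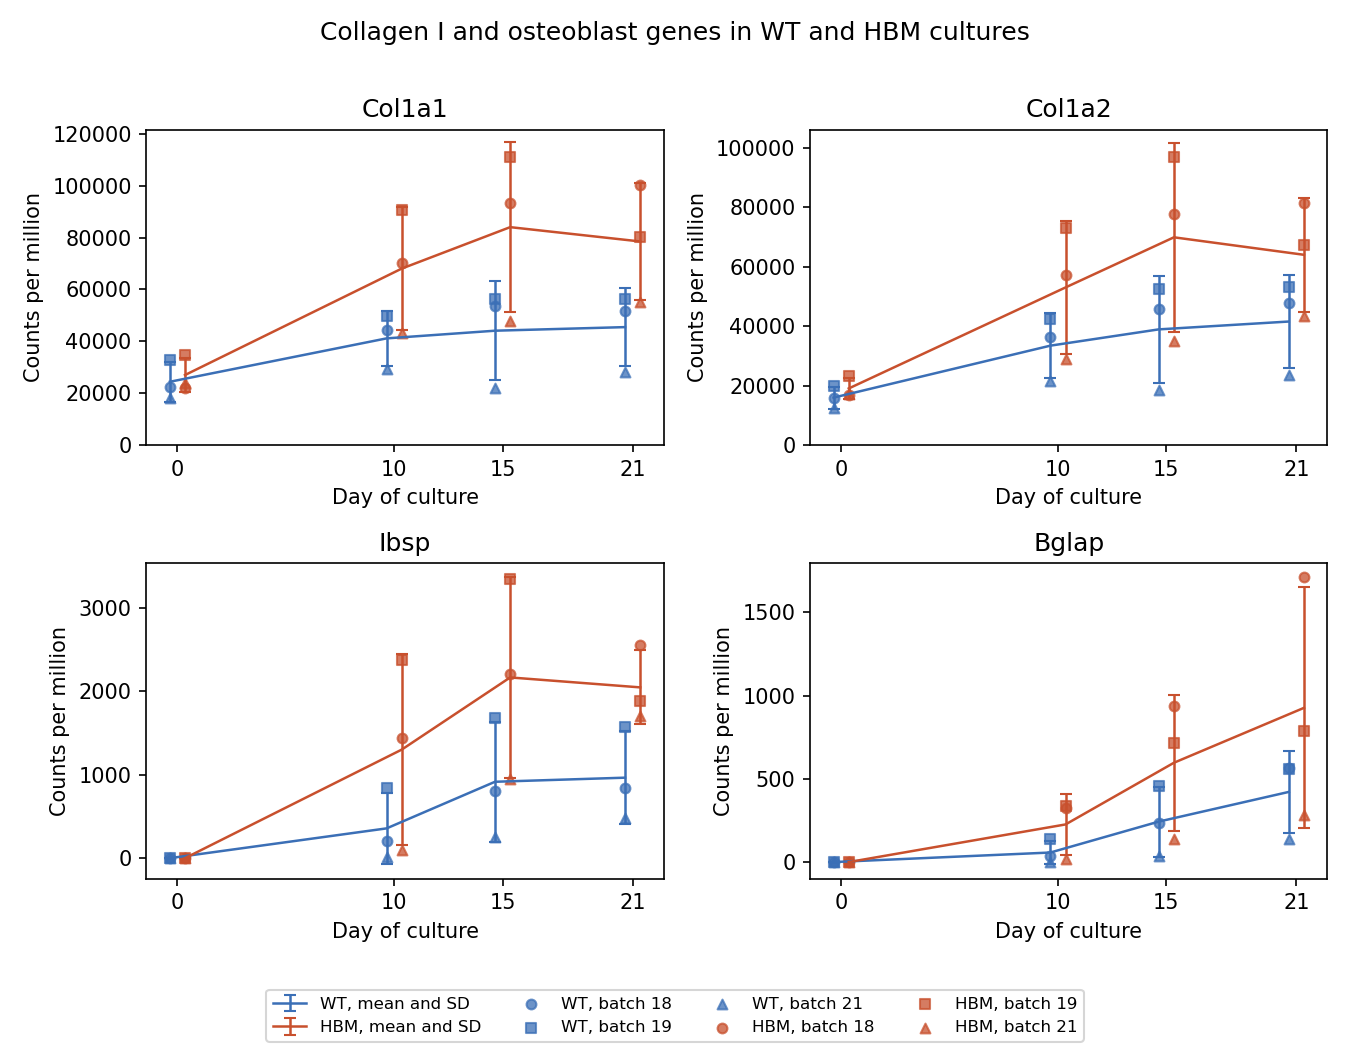
Levels in CPM, on linear axes, of Col1a1, Col1a2, Ibsp and Bglap against day of differentiation in WT and HBM cultures. Points are single cultures, lines join the group means and error bars are SD. Col1a1 stands at 41200 CPM in WT and 68100 in HBM at day 10, on average, and at 24400 and 27000 at day 0.

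The change from day 0 to day 10 in WT cultures answers what the first stretch of differentiation does in normal osteoblasts (3 cultures per day). Several genes of mineralizing osteoblasts rose, although of the 13 mineralization regulators 6 rose and 2 fell and neither that list (camera adjusted p = 0.259, and adjusted p = 0.746 with an estimated correlation) nor the osteocyte list (0.0582; adjusted p = 0.482 with an estimated correlation) passed. Ibsp rose 1600-fold (log2 change 10.65 ± 1.5 SE, adjusted p = 0.000132) and Bglap 428-fold (adjusted p = 0.00155), and Dmp1 rose 24.5-fold (adjusted p = 0.00478). Smpd3, a sphingomyelinase needed for mineralization, went from 1.05 ± 0.228 to 65 ± 73.4 CPM (adjusted p = 0.00138). Alpl rose by a log2 of 3.77 ± 1.1 (adjusted p = 0.0191). That call was lost without the WT library of batch 18 at day 0 (0.0609), of batch 19 at day 0 (0.0657) or of batch 19 at day 10 (0.058). The collagen I genes themselves did not pass: Col1a1 was at a log2 change of 0.75 ± 0.41 (adjusted p = 0.186) and Col1a2 at 1.07 ± 0.46 (0.0907). With the culture as a block they gave 0.0136 and 0.00302. Pcolce gave 0.0712 and 0.00609 with the block, Bmp1 0.26 and 0.0753, and Sost, with no count at day 0, 0.068 and 0.00483. DESeq2 called Col1a2 (0.0444) and Pcolce (0.0392).

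Of the 16592 genes tested, 2003 rose and 2330 fell between days 0 and 10 in WT, and 1931 of these changed at least 2-fold. Among the largest increases was the amino acid transporter Slc36a2, with no count at day 0 and 6.04 ± 5.92 CPM at day 10, at least 76.5-fold against a floor of 3 counts per library. The macrophage scavenger receptor Marco rose from 0.229 ± 0.271 to 109 ± 93.2 CPM (adjusted p = 0.000218) and the lysozyme gene Lyz1 from 0.158 ± 0.205 to 44 ± 11.3 (1.31e-05). The largest decreases were in Trib3, a stress-induced pseudokinase, from 59.5 ± 50.4 to 1.59 ± 0.653 CPM, Serpinb2, an inhibitor of plasminogen activators, and the cystine transporter Slc7a11. The prostaglandin synthase Ptgs2 fell from 61.3 ± 20.3 to 4.18 ± 0.454 CPM and the growth factor Fgf9 from 14 ± 2.73 to 0.974 ± 0.313. The cationic amino acid transporter Slc7a3 fell by a log2 of 3.95, a call lost without the WT libraries of batch 18 at day 0 (0.086) or of batches 18, 19 and 21 at day 10 (0.063, 0.0596 and 0.0799). With the culture as a block 3258 rose and 3120 fell. The number of genes was 2880 without the WT day 10 library of batch 19. It was 393 in a model of these 6 libraries alone, where Bglap, Dmp1 and Alpl gave 0.0556, 0.079 and 0.121.

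Matrix genes moved by list in the same WT step. Of 12 small leucine-rich proteoglycans, 9 rose over all genes and 9 adjusted over the list alone, among them decorin, Dcn, from 204 ± 88.6 to 1550 ± 277 CPM. That list had an adjusted p of 3.64e-06 (camera), and adjusted p = 0.256 with an estimated correlation. Of 17 fibrillar and fibril-associated collagens 7 rose, 8 adjusted over the list alone, led by Col14a1 with a 16.8-fold change and Col27a1 with a 6.35-fold change (list adjusted p = 2.89e-05, and adjusted p = 0.323 with an estimated correlation). Of 22 osteoblast genes 9 rose and 3 fell, 12 adjusted over the list alone (0.00909; adjusted p = 0.605 with an estimated correlation). Of 23 Wnt pathway genes 7 rose, 11 adjusted over the list alone, with the Wnt modulators Sfrp2 and Rspo2 22.2-fold and 7.26-fold up (0.00909; adjusted p = 0.262 with an estimated correlation). Of 5 lysyl oxidases, which crosslink collagen, Loxl2 and Loxl3 fell to 0.327 and 0.352 of their day 0 level, 2 adjusted over the list alone (0.0086; adjusted p = 0.262 with an estimated correlation). In the unfolded protein response list 8 of 22 fell, 9 adjusted over the list alone, such as the chaperone Canx and asparagine synthetase, Asns (0.0072; adjusted p = 0.278 with an estimated correlation). Of 20 glycolysis and hypoxia genes 7 fell and 1 rose, 10 adjusted over the list alone, with Eno1 and Pkm at 0.386 and 0.463 of day 0 (0.00136; adjusted p = 0.507 with an estimated correlation).

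Markers of other cell types moved beside these in WT. All 10 adipocyte markers had higher values at day 10, and 3 passed, 3 adjusted over the list alone. They included the regulator Cebpa, 5.39-fold up, and lipoprotein lipase, Lpl, 12.3-fold up. The median log2 change of the list was 4.52, or 3.57 with genes absent at day 0 held at the floor (0.000482; adjusted p = 0.323 with an estimated correlation). All 11 macrophage markers had higher values, with a median log2 of 2.94, 2 passing over all genes and 0 adjusted over the list alone in edgeR, against 11 with the culture as a block (0.000699; adjusted p = 0.482 with an estimated correlation). The 8 osteoclast markers had a median log2 of 1.5, with 3 past the threshold and 3 adjusted over the list alone. The list's adjusted p was 0.0196 and was lost without the WT day 0 library of batch 21 (0.0764), and was adjusted p = 0.323 with an estimated correlation. Cathepsin K, Ctsk, rose 2.08-fold, which was lost without the WT day 10 library of batch 18 (adjusted p = 0.0516).

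The same step was also tested in HBM cultures (3 per day). Ibsp rose 3090-fold (log2 11.59 ± 1.5, adjusted p = 7.36e-05), and Bglap, Dmp1 and Alpl rose by log2 changes of 11.15 ± 1.9, 6.69 ± 1.2 and 6.14 ± 1.3. Pcolce rose from 731 ± 43.8 to 1610 ± 389 CPM (adjusted p = 0.00757), while Bmp1 stood at 254 ± 15.2 and 422 ± 121 (0.065, 0.0373 in DESeq2 and 0.00558 with the culture as a block). Col1a1 rose 2.51-fold, from 27000 ± 6730 to 68100 ± 23600 CPM (adjusted p = 0.0248), and Col1a2 from 19000 ± 3520 to 53000 ± 22400 (0.0243). The Col1a1 call was lost without the HBM day 0 libraries of batch 18 (0.0937) or 21 (0.0663) or the day 10 libraries of batch 18 (0.0589) or 19 (0.0967). For Col1a2 the same 4 libraries gave 0.0831, 0.064, 0.0614 and 0.0976. Sost, with no count at day 0, was at least 86.9-fold higher at day 10 (adjusted p = 0.0443). This was lost without any of the day 0 libraries of batches 18, 19 and 21 (0.111, 0.108 and 0.0872) or the day 10 libraries of batches 18 and 19 (0.0733 and 0.0987).

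Of 16592 genes 2338 rose and 2065 fell in HBM, 2200 of them at least 2-fold. The lectin gene Cd22 and Asb10, both without counts at day 0, were at least 58.9-fold and at least 59.4-fold higher, and the lipid droplet gene Plin1 at least 87.4-fold (adjusted p = 0.0446). The Plin1 call was lost without the day 0 libraries of batches 18, 19 and 21 (0.114, 0.11 and 0.0897) or the day 10 library of batch 18 (0.353). The largest decreases were in Speer3, Trib3, Trim66, the interleukin 18 receptor gene Il18rap, the cadherin Cdh10 and the guidance factor Sema3e, which fell from 178 ± 37.4 to 8.09 ± 6.87 CPM. The Trib3 call was lost without the day 10 libraries of batch 18 (0.054) or 21 (0.0571), and that of Trim66 without those of batch 18 (0.0514) or 19 (0.0546). With the culture as a block 3406 rose and 2936 fell. Without the HBM day 0 library of batch 18 the step gave 2880 genes, and a model of these 6 libraries alone gave 2021, where Col1a1, Col1a2 and Trim66 gave 0.0593, 0.0564 and 0.0566.

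In HBM, 9 of 12 small leucine-rich proteoglycans rose, 9 adjusted over the list alone, with lumican, Lum, 7.54-fold and Dcn 10.1-fold up (median log2 2.54, or 2.52 at the floor, list adjusted p = 3.17e-07, and adjusted p = 0.183 with an estimated correlation). Of 17 fibrillar and fibril-associated collagens 10 rose, 12 adjusted over the list alone, including Col14a1 and Col27a1 (4.09e-06; adjusted p = 0.318 with an estimated correlation). Of 22 osteoblast genes 13 rose and 1 fell, 16 adjusted over the list alone (0.000112; adjusted p = 0.516 with an estimated correlation), and of 9 osteocyte genes 5 rose, 6 adjusted over the list alone. The osteocyte list, with a median log2 of 6.41, or 3.4 at the floor, gave 0.0122, and adjusted p = 0.356 with an estimated correlation. Of 28 genes of procollagen modification and processing 11 rose and 2 fell, 14 adjusted over the list alone. Among them were Adamts2, the protease of the N-propeptide, 3.77-fold up, and Crtap, part of the prolyl 3-hydroxylation complex, 2.13-fold up (0.005; adjusted p = 0.527 with an estimated correlation). Of 23 Wnt pathway genes 9 rose, 10 adjusted over the list alone (0.00689; adjusted p = 0.29 with an estimated correlation). Of 5 lysyl oxidases Loxl2 and Loxl3 fell, 2 adjusted over the list alone (0.0187; adjusted p = 0.318 with an estimated correlation), a list call lost without the day 10 library of batch 21 (0.0561). Of 10 adipocyte markers 6 rose, 9 adjusted over the list alone (median log2 6.62, or 5.52 at the floor, 0.000112, and adjusted p = 0.318 with an estimated correlation). Of 11 macrophage markers 4 rose, 10 adjusted over the list alone (0.000588; adjusted p = 0.516 with an estimated correlation), and of 8 osteoclast markers 4 rose, 4 adjusted over the list alone (0.005; adjusted p = 0.29 with an estimated correlation).

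The changes of both genotypes from day 0 to day 10 overlapped. Of the genes that rose, 1526 were shared, against 282 for independent lists of these sizes, and of those that fell, 1316 against 290, with 0 genes going opposite ways. Libraries of the same batch deviated together within a day, which can raise this overlap above that of independent cultures. Across the 16592 genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson r of 0.903. The interaction test given below is the test of a difference between them.

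Between days 10 and 15 the bone genes had higher values in both genotypes without any single gene passing in edgeR. In WT, Bglap stood at 57.5 ± 70.3 and 243 ± 210 CPM (log2 2.08 ± 1.2) and Ibsp at 357 ± 429 and 915 ± 721 (3 cultures per day). In HBM they stood at 226 ± 182 and 597 ± 410 and at 1300 ± 1140 and 2160 ± 1200 CPM. The counts of genes were 0 in WT (143 at an unadjusted p under 0.05) and 0 in HBM (90), and 0 in DESeq2 for both. A fit of days 10 to 21 with the culture as a block, chosen after seeing the data, gave 39 higher and 26 lower in WT and 17 higher and 1 lower in HBM. Among genes open to naming, the smallest p in WT belonged to the heparanase gene Hpse, Hebp1 and the macrophage receptor Vsig4 among higher values, and to fibrillin 2, Fbn2, from 280 ± 50.4 to 146 ± 33.4 CPM, Nphp4 and Grb10 among lower ones. In HBM it belonged to Dtna, Adgrf5 and Tvp23b and to Hs3st3a1, Ttyh3 and Mllt1.

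Several lists passed in the step from day 10 to day 15. The osteocyte list had a median log2 of 1.28 in WT (adjusted p = 0.00017, and adjusted p = 0.24 with an estimated correlation) and 1.12 in HBM (4.79e-06, and adjusted p = 0.173 with an estimated correlation). With the culture as a block and an estimated correlation it gave 0.0409 in HBM and did not pass in WT (0.071). The osteoblast list had medians of 0.56 (7.54e-06; adjusted p = 0.543 with an estimated correlation) and 0.38 (4.79e-06; adjusted p = 0.55 with an estimated correlation), and the mineralization regulators 0.51 (7.39e-06; adjusted p = 0.24 with an estimated correlation) and 0.32 (0.00138; adjusted p = 0.55 with an estimated correlation). All 25 cell cycle genes had lower values in both genotypes, such as Mcm2, at 31 ± 5.86 and 24.9 ± 7.68 CPM in WT, with medians of -0.41 (1.07e-06; adjusted p = 0.593 with an estimated correlation) and -0.42 (1.09e-09; adjusted p = 0.55 with an estimated correlation). All 10 adipocyte markers had higher values in WT, with a median of 1.66 (1.07e-06; adjusted p = 0.24 with an estimated correlation, and 0.0313 with the culture as a block). All 21 interferon response genes had lower values in WT, among them Stat2 at 51.7 ± 1.26 and 36.6 ± 2.98 CPM (6.34e-05; adjusted p = 0.612 with an estimated correlation), and 19 of 21 in HBM (0.00139; adjusted p = 0.793 with an estimated correlation). No member of these lists passed alone in edgeR, over all genes or adjusted over the list alone, whereas with the culture as a block 6 adipocyte markers, 1 osteoblast and 1 osteocyte gene in WT and 5 osteocyte genes in HBM passed adjusted over the list alone.

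These calls rest on few libraries. In WT the osteoblast, osteocyte and mineralization calls were lost without the day 10 library of batch 21 (0.317, 0.152 and 0.145), and the osteoblast and osteocyte calls without the day 15 library of batch 19 (0.379 and 0.075). The WT cell cycle call was lost without the day 10 library of batch 19 (0.496) or the day 15 library of batch 21 (0.0919). In HBM the osteoblast, osteocyte, mineralization and interferon calls were lost without the day 10 library of batch 21 (0.955, 0.105, 0.955 and 0.193). The HBM osteoblast call also went without the day 15 library of batch 19 (0.131), the cell cycle call without that of batch 21 (0.0541), and the interferon call without the day 10 library of batch 19 (0.0896) or the day 15 library of batch 18 (0.297).

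Between days 15 and 21 cell cycle genes again had lower values and, in WT, osteoclast markers higher ones. All 25 cell cycle genes were lower in WT, with a median log2 of -0.73 (adjusted p = 1.54e-10, and adjusted p = 0.817 with an estimated correlation), and in HBM, with a median of -0.77 (3.6e-17, and adjusted p = 0.92 with an estimated correlation). Their member Aurka was at 11.3 ± 6.25 and 5.87 ± 1.07 CPM in WT. The WT call was lost without the day 15 library of batch 19 (0.572). All 8 osteoclast markers were higher in WT, with the proton pump subunit Atp6v0d2 at 13 ± 8.91 and 42.8 ± 32.4 CPM and a median log2 of 0.82 (1.01e-06; adjusted p = 0.0652 with an estimated correlation, and 0.0026 with the culture as a block). No osteoclast marker passed over all genes or adjusted over the list alone in edgeR, and 3 did adjusted over the list alone with the block. Immediate early and heat shock genes were lower in WT, 14 of 15 (1.01e-06; adjusted p = 0.817 with an estimated correlation), as for Egr1 at 153 ± 69.6 and 55.5 ± 20 CPM, a call lost without the WT day 15 library of batch 21 (0.145). In HBM 11 of 15 were lower (0.0376; adjusted p = 0.92 with an estimated correlation), a call lost without the HBM libraries of batches 18 and 21 at day 15 (0.191 and 0.798) or of batches 18 and 19 at day 21 (0.265 and 0.341).

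No single gene passed between days 15 and 21 in edgeR, in WT (86 at an unadjusted p under 0.05) or HBM (80), nor in DESeq2. Of the genes open to naming, the smallest p in WT belonged to Hpse, at 23.9 ± 3.96 and 45.1 ± 11.6 CPM, the collagen of hypertrophic cartilage Col10a1 and Lmo7, and to the lower Ddias, Tead2 and Ptgs2. In HBM it belonged to the actin binder Avil, Tom1 and Arid5a and to the lower Mrpl39, Ddx19a and Ttc21b. The fit of days 10 to 21 with the culture as a block gave 0 genes in HBM and 1 in WT. That gene was Clec7a, a receptor of myeloid cells, at 6.73 ± 5.15 and 14.7 ± 9.61 CPM (log2 1.17 ± 0.14, adjusted p = 0.0168), and it was chosen after its values were seen.

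At day 0, before differentiation starts, cartilage genes had lower values in HBM than in WT (3 cultures per genotype). Collagen IX chains Col9a2 and Col9a3 were at 3.91 ± 2.64 and 46 ± 54.9 CPM against 23.5 ± 20.7 and 203 ± 248 in WT, and the matrix protein Comp at 28.6 ± 27.1 against 114 ± 138. In the paired fit these passed, with adjusted p of 0.0495, 0.0489 and 0.0477, as did chondromodulin, Cnmd (log2 -2.59 ± 0.42, adjusted p = 0.0489), which was lower in batches 19 and 21 (-3.48 and -2.15) but not in batch 18 (0.21). Outside cartilage, the growth factor binder Igfbp2 was at 1020 ± 570 against 2090 ± 1070 CPM (paired 0.0477), the matricellular Ccn2 at 597 ± 359 against 1150 ± 682 (0.0489) and the osteoclast phosphatase Acp5 at a paired log2 of -1.01 ± 0.11 (0.00929). None of the paired calls named in this paragraph passed in that fit without batch 19 or 21, among them Acp5 (0.276 and 0.13). Without pairing its log2 was 1.31 when the WT library of batch 19 was left out and -3.3 when the HBM library of that batch was. The 2 genes higher in HBM in that fit were Ccdc3, by a log2 of 0.99 ± 0.14 (0.0347), and the integrin Itgb3, by 0.68 ± 0.11 (0.0489). Without pairing the smallest adjusted p of any gene was 0.23. Among genes open to naming, the smallest p belonged to Phactr4, Asph and Lmo7 for higher values and Tmem205, Selenbp1 and Wscd2 for lower ones, each with an adjusted p of 0.901.

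At day 0 no gene fixed in advance passed. Col1a1 differed by a log2 of 0.15 ± 0.41 (paired 0.16 ± 0.14, adjusted p = 0.521), Col1a2 by 0.25 ± 0.45, Bmp1 by 0.00 ± 0.28 and Pcolce by -0.29 ± 0.28. Alpl was at 4.63 ± 6.39 against 10.9 ± 15 CPM, with a log2 between -3.51 and 1.02 on leaving out single libraries, and neither group had a count of Sost. Bglap, Ibsp and Dmp1 were at 0.0999 ± 0.0591, 0.418 ± 0.0661 and 0.58 ± 0.178 CPM in HBM, and at 0.133 ± 0.0776, 0.223 ± 0.0762 and 0.937 ± 0.516 in WT. No gene passed in edgeR without pairing (699 at an unadjusted p under 0.05) or in DESeq2, and 20 did in the paired fit, 2 higher and 18 lower. With the block chosen beforehand, 1 batch term for all days, 0 genes passed in edgeR at day 0 (1392 at an unadjusted p under 0.05), and likewise 0 at days 10, 15 and 21 (1259, 1005 and 1084). The paired fit, added after the data had been seen, gave 55 genes without batch 18, 2 without batch 19 and 0 in edgeR without batch 21 (3082 at an unadjusted p under 0.05). A paired model of these 6 libraries alone gave 0 (534). Of the 28 lists, only the 12 chondrocyte markers passed. They had a median log2 of -1.15, with 11 lower values, 0 members past the threshold in edgeR over all genes or adjusted over the list alone, and 3 and 6 in the paired fit (camera 0.000229; adjusted p = 0.996 with an estimated correlation, and 0.478 in the paired fit). That call was lost without the HBM library of batch 18 (0.0581) or the WT libraries of batch 19 (0.0768) or 21 (0.0733), and the medians within batches 18, 19 and 21 were -0.162, -1.51 and -1.45. The paired fit added the small leucine-rich proteoglycans, lower (0.0392; adjusted p = 0.604 with an estimated correlation), with 4 of 12 lower adjusted over the list alone.

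At day 10, once mineralization genes were on, most osteoblast genes had higher values in HBM than in WT (3 cultures per genotype). Bglap was at 226 ± 182 CPM against 57.5 ± 70.3 and Ibsp at 1300 ± 1140 against 357 ± 429, paired log2 differences of 2.51 ± 0.38 and 2.17 ± 0.31 (paired adjusted p = 0.0143 for each), higher in 3 of 3 batches. Col1a1 was at 68100 ± 23600 against 41200 ± 10500 CPM (paired log2 0.70 ± 0.14, adjusted p = 0.0353) and Col1a2 at 53000 ± 22400 against 33400 ± 10800 (0.62 ± 0.13, 0.0459). These 4 calls were lost in the paired fit without batch 18 (Bglap 0.123, Ibsp 0.116, Col1a1 0.283, Col1a2 0.366) or 21 (0.161, 0.127, 0.14 and 0.145), and the collagen calls also without batch 19 (0.242 and 0.273). Bmp1 and Pcolce, which act on the C-propeptide, did not pass, at paired log2 differences of 0.29 ± 0.09 (0.163) and 0.13 ± 0.13 (0.701). Alpl (0.96 ± 0.29, 0.137), Dmp1 (1.37 ± 0.44, 0.154) and Sost (1.61 ± 0.59, 0.232) did not either. Without pairing every gene had an adjusted p of 1: Col1a1 differed by 0.73 ± 0.41 and Bglap by 1.98 ± 1.2.

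Among the genes with the largest paired difference at day 10, the higher ones were the hypoxia gene Ankrd37, the neuropeptide Gal, Lingo3, Bglap2, the Wnt inhibitor Dkk1 and Ccdc194. Dkk1 was at 15.8 ± 17.7 CPM in HBM against 4.01 ± 5.71 (paired adjusted p = 0.0143). The lower ones were Vat1l, Fam107a, Hoxaas2, the neuronal adhesion genes Nfasc and Cntnap2, Meltf, the muscle gene Mybpc1 and the keratin Krt87, with Vat1l at 0.638 ± 0.566 against 5.78 ± 4.18 CPM. Bglap2 shares most of its sequence with Bglap, an expressed neighbour overlaps Ankrd37, and Hoxaas2 lies antisense to Hoxa3, so reads of these are uncertain. Signalling genes past the threshold in the paired fit included Bmp2, 1.68-fold higher (0.0169), Tgfb1, 1.45-fold (0.0143), the Wnt genes Tcf7, 2.51-fold (0.0233), and Wnt10b, 2.43-fold (0.037), and the cytokine Lif, 1.86-fold (0.0428). Their lists did not pass. Of 24 BMP and TGF-beta genes 11 had higher and 13 lower values (camera adjusted p = 0.705, paired 0.489), and 1 passed as lower in the paired fit. Of 23 Wnt genes 10 had higher and 13 lower values (0.932 and 0.264). The cartilage regulator Sox9 was at 0.652 of WT (0.0143) and tenomodulin, Tnmd, a tendon gene, at 0.691 (0.0393). Without pairing the smallest p among genes open to naming belonged to Arhgdig, Bop1 and Myc and to the lower Neto2, Itga1 and Gpd2. No gene passed in edgeR (478 at an unadjusted p under 0.05), against Neto2 (log2 -1.12, 0.0438) and Arhgdig (1.15, 0.0376) in DESeq2 and 214 genes in the paired fit, 110 higher and 104 lower. That fit gave 42, 25 and 5 genes without batches 18, 19 and 21, and a paired model of these 6 libraries alone 6. None of the calls of named genes given here passed without batch 21 or in that model.

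By list at day 10, 19 of 22 osteoblast genes were higher in HBM, with a median log2 of 0.80 (camera 1.87e-08). In the paired fit 10 passed over all genes and 16 adjusted over the list alone, and the list gave 0.0561 with an estimated correlation in that fit. The 13 mineralization regulators (median 1.07, 0.000333) included Phospho1, a phosphatase that a neighbour overlaps, 3.31-fold higher, and Smpd3, 3.2-fold higher, with 4 in the paired fit and 6 adjusted over the list alone. The 9 osteocyte genes had a median of 0.996 (0.0296), with 1 in the paired fit and 2 adjusted over the list alone. Of 28 procollagen modification and processing genes 23 had higher values (1.6e-05), with the hydroxylases P4ha1 and P3h2 2.51-fold and 2.14-fold higher. There 2 passed in the paired fit, and 12 higher and 1 lower adjusted over the list alone. Of 22 unfolded protein response genes 20 had higher values (0.000458), with the stress factor Creb3l1 1.49-fold higher, 1 in the paired fit and 2 adjusted over the list alone. Of 20 glycolysis and hypoxia genes 18 had higher values (1.83e-06), 2 in the paired fit and 5 adjusted over the list alone. The 12 chondrocyte markers had a median of -1.23 (1.3e-05), with 2 lower in the paired fit and 8 adjusted over the list alone. Each of these 7 lists had adjusted p = 0.475 with an estimated correlation, and without pairing no member passed over all genes and 1, a chondrocyte marker, adjusted over the list alone.

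The osteocyte call at day 10 was lost without the HBM libraries of batch 18 (0.0955) or 19 (0.697) or the WT libraries of batch 18 (0.115) or 21 (0.615). The glycolysis call was lost without the HBM library of batch 19 (0.202) and the mineralization call without the WT library of batch 21 (0.253). The paired fit called 9 lists, adding the fibrillar collagens, higher (0.000274; adjusted p = 0.142 with an estimated correlation), with 3 higher over all genes, Col1a1 and Col1a2 among them, and 6 higher and 1 lower adjusted over the list alone. It also added the cell cycle genes, higher (5.05e-05; adjusted p = 0.49 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone. Of 10 adipocyte markers 9 had higher values in HBM at day 10, with a median log2 of 1.22, and the list did not pass (0.378).

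**Figure D3:**
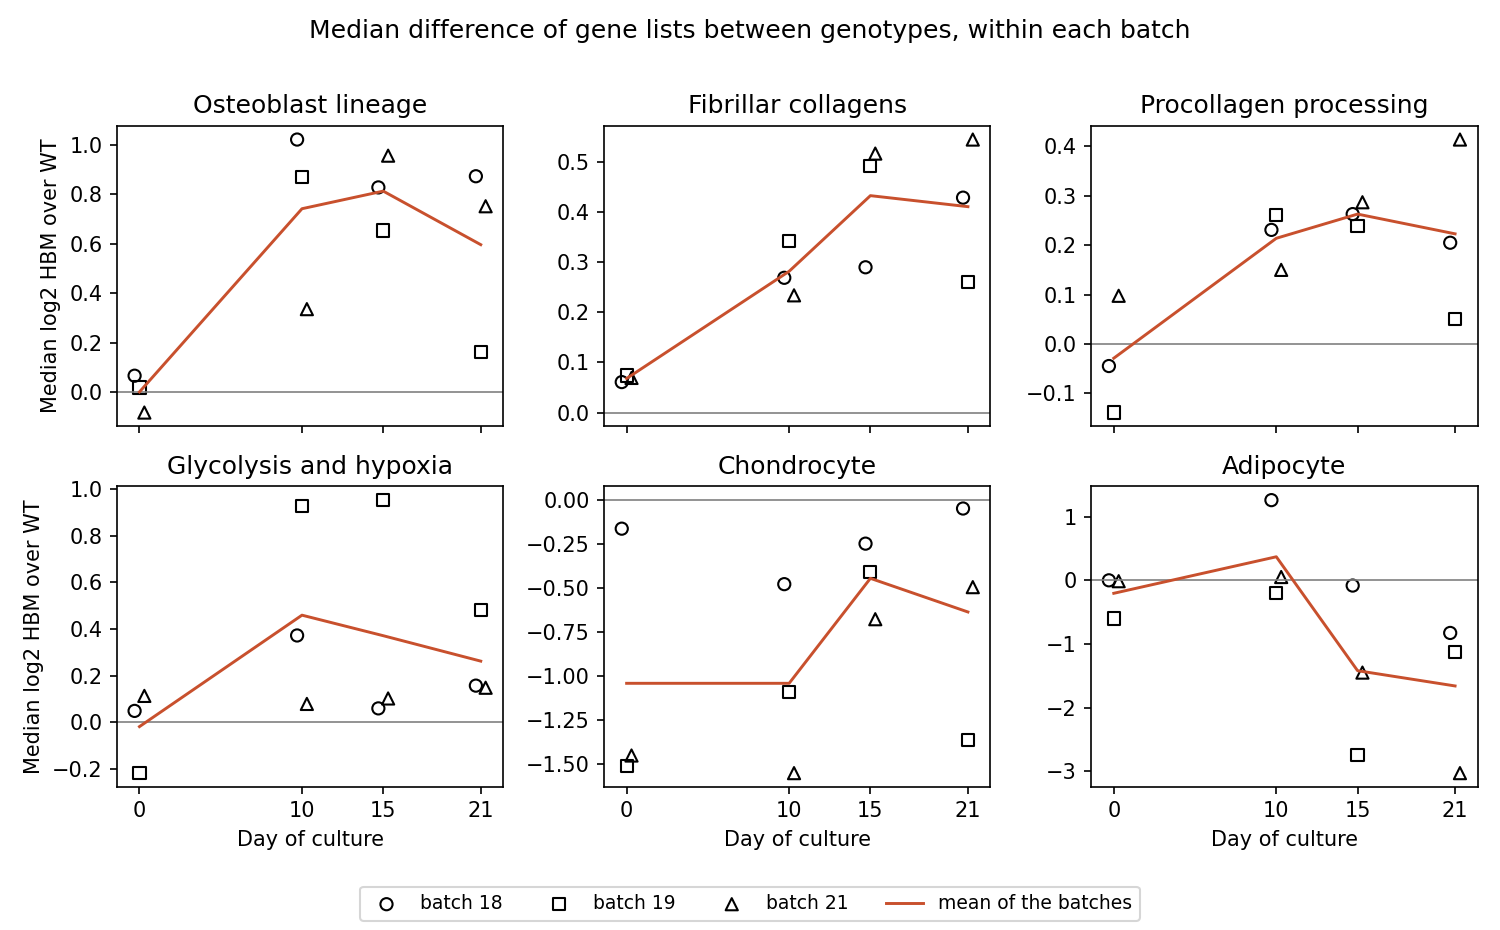
Median log2 difference, HBM minus WT, of the members of gene lists on each day. Points are batches 18, 19 and 21 and lines join the means of the 3. The osteoblast list lies at -0.0811 to 0.0675 at day 0 and at 0.336 to 1.02 at day 10.

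At day 15 most collagen and osteoblast genes again had higher values in HBM (3 cultures per genotype). In the paired fit 3 of 22 osteoblast genes and 2 of 17 fibrillar and fibril-associated collagens passed, and without pairing 0 did. Col1a1 was at 84000 ± 32600 CPM against 44100 ± 19000 (paired log2 0.96 ± 0.14, adjusted p = 0.0241) and Col1a2 at 69900 ± 31800 against 38900 ± 18100 (0.86 ± 0.13, 0.0288), with higher values in 3 of 3 batches. Without batches 18, 19 and 21 the paired fit gave 0.13, 0.073 and 0.244 for Col1a1 and 0.187, 0.0831 and 0.246 for Col1a2. Sp7, the osteoblast transcription factor osterix, was 2.15-fold higher (0.0348). Bglap, at 597 ± 410 against 243 ± 210 CPM, and Ibsp, at 2160 ± 1200 against 915 ± 721, did not pass (paired 0.0842 and 0.0611). Nor did Bmp1 (log2 0.38 ± 0.09, 0.105), Pcolce (0.10 ± 0.13, 0.852), Alpl (0.14), Dmp1 (0.235) and Sost (0.113). Genes higher in HBM in the paired fit by the largest folds were Adm2, Tfap2b, stanniocalcin 2, Stc2, at 14.1 ± 13.4 against 3.6 ± 3.01 CPM, Dkk1, Ephx4, the glycine transporter Slc6a9, Shox2 and the citrate transporter Slc13a5, at 142 ± 52.5 against 57.1 ± 33.5. Lower were Fam107a, Hoxaas2, Cntnap2, the transcription factor Mecom, at 4.46 ± 1.37 against 12.3 ± 3.79 CPM, Tspan8 and Itih2. Bmp2 was 1.79-fold and Creb3l1 1.71-fold higher (0.0241 and 0.0223). No gene passed without pairing (346 at an unadjusted p under 0.05) or in DESeq2, with the smallest p among genes open to naming in Mboat1, Filip1l and Nbas, and in the lower Rhou, Neto2 and Wnt11. The paired fit gave 51 genes, 37 higher and 14 lower, and 10, 18 and 1 without batches 18, 19 and 21, where without batch 21 no gene named here passed. A paired model of these 6 libraries alone gave 730, with Sp7 not among them (0.0637).

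At day 15, 20 of 22 osteoblast genes had higher values in HBM (median log2 0.86, camera 1.78e-09), and all 9 osteocyte genes did (median 0.96, 0.00294). These gave adjusted p = 0.383 with an estimated correlation, and 0.0191 and 0.0218 in the paired fit, where 3 and 1 members passed, 19 and 5 adjusted over the list alone. Of 17 fibrillar and fibril-associated collagens 15 were higher (3.77e-06; adjusted p = 0.383 with an estimated correlation, and 0.0191 in the paired fit), 2 in the paired fit and 7 adjusted over the list alone. The 5 lysyl oxidases (0.00294; adjusted p = 0.323 with an estimated correlation) had Loxl4 2.48-fold higher, 0 in the paired fit and 3 adjusted over the list alone. The 28 procollagen genes (1.05e-07; adjusted p = 0.383 with an estimated correlation) had 0 and 13, P4ha2 and P4ha1 among their smallest p, and the 13 mineralization regulators (0.00629; adjusted p = 0.499 with an estimated correlation) 0 and 7. The 22 unfolded protein response genes (5.27e-06; adjusted p = 0.152 with an estimated correlation) had 1 and 4, and the 20 glycolysis and hypoxia genes (1.34e-06; adjusted p = 0.499 with an estimated correlation) 0 and 5. Of 10 adipocyte markers 8 were lower, with a median of -0.38, or -0.92 in the paired fit (0.00629 without pairing, and adjusted p = 0.53 with an estimated correlation). They had 0 and 0 members, with Cebpa at 53.3 ± 8.92 against 70.7 ± 7.35 CPM. Without pairing no member of any of these lists passed over all genes or adjusted over the list alone.

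Without the WT day 15 library of batch 21 the calls of the osteocyte, mineralization, procollagen, lysyl oxidase and fibrillar collagen lists were lost (0.0522, 0.326, 0.0522, 0.117 and 0.246). Without the HBM library of batch 19 those of the osteocyte, glycolysis and adipocyte lists were (0.0536, 0.416 and 0.139), and the direction of the glycolysis list turned from higher to lower. The adipocyte call was also lost without the HBM library of batch 21 (0.361) or the WT library of batch 18 (0.277). The paired fit added chondrocyte markers, 9 of 12 lower (0.00554; adjusted p = 0.415 with an estimated correlation), 3 adjusted over the list alone, cell cycle genes, 23 of 25 higher (0.000633; adjusted p = 0.619 with an estimated correlation), and osteoclast markers, 7 of 8 higher (0.049; adjusted p = 0.159 with an estimated correlation), the last 2 with 0 members.

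At day 21 HBM cultures had higher values of collagen genes and lower ones of adipocyte and interferon genes (3 cultures per genotype). Col1a1 was at 78500 ± 22600 CPM against 45500 ± 15100 (paired log2 0.81 ± 0.14, adjusted p = 0.0401), higher in 3 of 3 batches but not passing without batch 18, 19 or 21 (0.386, 0.0511 and 0.252), and Col1a2 at 64000 ± 19200 against 41500 ± 15800 (0.66 ± 0.13, 0.0645). Bmp1 (0.36 ± 0.10, 0.119), Pcolce (0.12 ± 0.13, 0.736), Alpl (0.89 ± 0.29, 0.206), Bglap (1.04 ± 0.34, 0.206), Ibsp (1.24 ± 0.30, 0.105), Dmp1 (0.78 ± 0.42, 0.448) and Sost (1.48 ± 0.43, 0.173) did not pass. The largest higher values past the threshold in the paired fit were in the actin binder Avil, Cabp1, the steroid enzyme Hsd17b1, Stc2, Slc6a9, Wnt10b, at 16.5 ± 4.91 against 6.56 ± 3.42 CPM, Fosl1, which a neighbour overlaps, and Shox2. The lower ones were Fam107a, the basement membrane gene Hmcn1, at 8.53 ± 4.85 against 28 ± 18 CPM, Arhgef16, Mecom, Shroom3 and Sh3rf2. Bmp2 was 1.61-fold and Creb3l1 1.63-fold higher (0.0418 and 0.0272). No gene passed in edgeR without pairing (352 at an unadjusted p under 0.05), with the smallest p among genes open to naming in Taf15, Btg3 and Mical2 and in the lower Neto2, Rhou and Wnt11. DESeq2 called 1 gene, Neto2 (log2 -1.17, 0.0369), and the paired fit 41, 27 higher and 14 lower. That fit gave 5, 130 and 2 genes without batches 18, 19 and 21, and a paired model of these 6 libraries alone 59. Of the paired calls named here, only Fam107a passed without batch 18 and only Avil without batch 21.

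By list at day 21, 20 of 22 osteoblast genes (median log2 0.52, camera 2.77e-05), 22 of 28 procollagen genes (4.39e-05) with the collagen chaperone Serpinh1 1.4-fold higher, 13 of 17 fibrillar and fibril-associated collagens (0.0017) and 18 of 20 glycolysis and hypoxia genes (0.00044), with Vegfa at 93.2 ± 54.3 against 50 ± 26.7 CPM, had higher values in HBM. Each of these 4 had adjusted p = 0.64 with an estimated correlation. In the paired fit 1, 0, 1 and 0 of their members passed, and 12, 8, 5 and 3 higher adjusted over the list alone, with 1 collagen lower. The 5 lysyl oxidases were all higher (0.00044; adjusted p = 0.275 with an estimated correlation), with Loxl3 1.32-fold higher, 0 in the paired fit and 4 adjusted over the list alone. Of 22 unfolded protein response genes 16 were higher (0.00186; adjusted p = 0.494 with an estimated correlation), 1 in the paired fit and 6 adjusted over the list alone. All 10 adipocyte markers were lower, with a median of -1.31 (4.17e-05; adjusted p = 0.494 with an estimated correlation), among them the regulator Pparg at 16.9 ± 5.13 against 24.8 ± 3.25 CPM and the fatty acid binder Fabp4 at 10.3 ± 12.8 against 27.3 ± 19.3. All 21 interferon response genes were lower, with a median of -0.46 (0.0121; adjusted p = 0.741 with an estimated correlation) and Oasl2 at 9.4 ± 0.562 against 14.4 ± 1.86 CPM. Chondrocyte markers were lower in 11 of 12 (0.0017; adjusted p = 0.64 with an estimated correlation). In the paired fit none of these 3 lists had a member past the threshold over all genes, and 3, 3 and 4 passed adjusted over the list alone, and without pairing no member of the 9 lists passed either way.

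Without the WT day 21 library of batch 21 the osteoblast, procollagen, fibrillar collagen and unfolded protein response calls were lost (0.0721, 0.109, 0.191 and 0.0681). The glycolysis call was lost without the HBM library of batch 19 (0.555) or the WT library of batch 18 (0.0558), the interferon call without the HBM or the WT library of batch 18 (0.0732 and 0.0544), and the chondrocyte call without the WT library of batch 19 (0.264). The paired fit added 6 lists. Of the osteocyte genes 7 of 9 (0.00117; adjusted p = 0.153 with an estimated correlation), of the mineralization regulators 9 of 13 (0.00113; adjusted p = 0.297 with an estimated correlation), of the BMP and TGF-beta genes 16 of 24 (0.0246; adjusted p = 0.16 with an estimated correlation) and of the immediate early genes 12 of 15 (0.00355; adjusted p = 0.258 with an estimated correlation) were higher, with 3, 3, 2 and 2 members adjusted over the list alone. All 11 macrophage markers (0.000503; adjusted p = 0.405 with an estimated correlation) and all 8 osteoclast markers (0.031; adjusted p = 0.153 with an estimated correlation) were lower, with 0 members of either past the threshold in edgeR.

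Of the genes past the threshold in the paired fit, 14 were higher and 5 lower in HBM on each of days 10, 15 and 21. Among the higher ones were Bmp2, Col1a1, Creb3l1, Mboat1, Slc13a5 and Stc2, and the lower ones were Fam107a, Mecom, Neto2, Shroom3 and Wnt11. At least 1 of these days called 235 genes. Of the 18 genes lower at day 0, 3 were lower at day 10, and none of the 2 higher ones was shared with a later day. The days sampled the same 3 pairs of cultures, so a call on several days is not a replication. In edgeR without pairing and with the planned block 0 genes passed on each day.

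Averaged over the 4 days, the collagen I and bone genes had higher values in HBM (3 cultures per genotype, counts summed over days). Col1a1 was at 64900 ± 17900 CPM against 38400 ± 12300, Col1a2 at 51800 ± 17000 against 32100 ± 11800, Alpl at 298 ± 119 against 158 ± 97.3 and Dmp1 at 49.1 ± 11.4 against 19.9 ± 7.2, and none passed with the batch as a block (0.0571, 0.0614, 0.0671 and 0.141). Neither did Bmp1 (0.108), Pcolce (0.637), Bglap (0.12), Ibsp (0.105) or Sost (0.0999). Dmp1 passed in DESeq2 (0.0325). No gene passed in edgeR without the block (540 at an unadjusted p under 0.05) or in voom (535), against 25 in DESeq2, 10 higher and 15 lower. With the block 36 passed, 23 higher and 13 lower, all close to the threshold (adjusted p from 0.047). Treating the 24 libraries as independent gave 38. The smallest p without the block, among genes open to naming, belonged to the tenascin Tnn, at 184 ± 29.6 against 70.8 ± 13.9 CPM, Ston2 and Mboat1, and to the lower Glis3, Neto2 and Itga1. DESeq2 called all 6, with adjusted p of 4.87e-06, 6.5e-05, 0.00149, 5.57e-06, 2.55e-05 and 0.00489. With the block the largest higher folds past the threshold were Ndufa4l2, 3.16-fold, Klhl30, Slc13a5, Hapln4, Lgi2, 2.34-fold, Kcnf1, the lysyl oxidase Loxl4, 2.15-fold, and Hspb7. The lower ones were Hoxaas2, Astn2, the cartilage collagen Col9a3 at 0.516 of WT, the laminin Lama1 (0.047), Nell1, Tspan8, the Wnt enhancer Rspo2 at 0.586 and Zic4. Without the block the log2 of Lama1 was -0.93, and 0.37 when the WT culture of batch 21 was left out. Bmp2 was 1.72-fold higher (0.0496). Within batches 18, 19 and 21 the log2 difference of Col1a1 was 0.78, 0.69 and 0.85.

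Whether the genotype difference changes with day was tested for each gene with 3 degrees of freedom. No gene passed in edgeR (99 at an unadjusted p under 0.05), in DESeq2 (133), or in the paired fit with a further term for the genotype difference of each batch (1577). The smallest p without pairing belonged to Flrt2, Neto2, Gpd2, the porphyrin transporter Abcb6, Cplane1, Cep162, Ptges3l, Rps26-ps1, the peroxidasin Pxdn and Dpm3. Neto2 differed by log2 values of 0.08, -1.12, -1.16 and -1.18 at days 0, 10, 15 and 21 (adjusted p = 1). In the paired fit the smallest p belonged to the growth factor gene Igf2 (adjusted p = 0.0651), followed by Ccn2, Bglap and Nupr1 (0.131 each). Without pairing the log2 differences on the 4 days were 0.79, -0.21, -0.35 and -1.1 for Igf2 and -0.44, 1.98, 1.29 and 1.14 for Bglap.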

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

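The tests on sex composition, on the course at days 10 and 15 to 21 against other batches, on fewer other cells and on a single WT culture, and all swaps of genotype labels within batches, were chosen after the result was seen; the other tests were planned.

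On some days every batch of a list's HBM to WT difference went one way and on another day every batch went the opposite way, and these differences between days were not tested. The mean of the batch medians of the mitochondrially encoded genes was -0.213 at day 0 and 0.0661 at day 15, a log2 difference of 0.279. For the osteoclast markers the means were -0.313, 0.19, 0.208 and -0.228 at days 0, 10, 15 and 21, so that day 0 differed from days 10 and 15 by 0.503 and 0.521, and day 21 from days 10 and 15 by -0.418 and -0.436. For skeletal muscle markers day 21, at 0.19, differed from day 10, at -0.358, by 0.547 and from day 15, at -0.158, by 0.348. These are 7 of 168 pairs of days, where random signs give 5.25.

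The first pattern is the higher values of the osteoblast list in HBM at days 10, 15 and 21. A further advanced course of HBM cultures stays open: the day 21 difference correlated across genes at 0.014, -0.00124 and -0.0949 with the WT change from day 10 to day 15, lower than the 0.24 to 0.394 of the same step and the 0.0833 to 0.298 of the step from day 15 to day 21 in single cultures against other batches, but what a smaller advance gives was not measured, and the bound of 0.1 set beforehand lies above 0.0833, and the differences at days 10 and 15 gave 0.173, 0.138 and 0.0631 and 0.116, 0.0344 and -0.00207. Fewer cells of other types in HBM may contribute at day 21, where all 5 marker lists were below 0 and lay within 1.43 ± 0.715 (SE), and stays open at day 15 (1.63 ± 0.812). At day 10 an equal loss of all 5 types is argued against, because only the chondrocyte markers had a mean below 0 (-1.04). They differed from the adipocyte markers, at 0.37, by 1.41 ± 0.266. These were the lowest and the highest list, picked from the same values, and unequal losses stay open at day 10. The sex composition of the pools stays open: only in batch 21 did both pools lack Xist, and the list's medians there, 0.336, 0.955 and 0.751 on the 3 days with a mean of 0.681, come from 1 pair of cultures. The genotype itself stays open as a hypothesis, and no test here parts it from other differences between the pooled cultures of the 2 lines.

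The second pattern is the lower values of cartilage genes in HBM at day 0. More cartilage RNA in the WT culture of batch 19 alone cannot be told apart from a difference of all cultures: the medians were -1.51 ± 0.466 (SE) there and -1.45 ± 0.434 in batch 21, but -0.162 ± 0.158 in batch 18, within 2 SE of 0. A smaller share of cartilage cells carried over into HBM cultures stays open too, because the log2 ratios of 8 cartilage genes had SDs of 1.17 and 1.05 in batches 19 and 21 but 0.482 in batch 18, and the spread that a single source of RNA gives was not measured. Col2a1, their most abundant gene, was at 1200, 15900 and 3790 CPM in the WT libraries of batches 18, 19 and 21 and at 755, 8770 and 1670 in HBM. The genotype is a hypothesis that no test here decides.

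The third pattern is the set of genes past the threshold in the paired fit at day 10. Strain variants carried along with the Col1a1 locus may account for part of it, if the change of the HBM line lies there, which the labels do not say. Of 311 genes within 10 Mb of Col1a1, 6 passed (1.93%), against 207 of 16280 elsewhere (1.27%), with a Fisher exact p of 0.3 (two-sided). The count near Col1a1, with Phospho1 among the 6, is too small to decide.

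The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. HBM against WT gave 0 genes at day 0, where the highest other split gave 1460, and 0 at days 10, 15 and 21 and on average, where the highest other gave 0. The split of 1460 genes set both batch 19 libraries with HBM of batch 18 against both batch 21 libraries with WT of batch 18, which points to a structure of the samples by batch; with the real labels the planned block of 1 batch term gave 0 and the paired fit 20. The change with day gave 0, with 25 in a split of HBM of batch 19 and both cultures of batch 18 against the rest. The step from day 0 to day 10 gave 4333 genes in WT and 4403 in HBM, with 0 in the highest other split, and the later steps gave 0 in the real and in the highest other split. For the gene lists the real and the highest other counts were 1 and 8 at day 0, 7 and 15 at day 10, 9 and 15 at day 15 and 9 and 14 at day 21. Only 3 of the other 9 splits part all 3 pairs of cultures, as the real one does, and they equal swaps of labels within batches. These, with the real labels, make 4, again too few: in the paired fit at days 0, 10, 15 and 21, and with the batch block on average, the real labels gave 20, 214, 51, 41 and 36 genes and the highest other 1, 0, 0, 1 and 0. For the lists at the 4 days these were 2, 9, 12 and 15 against 3, 12, 9 and 10.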

How the results depend on the processing

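The paired fit, its runs without a whole batch, the paired models of only 2 groups and the block on days 10 to 21 were chosen after seeing the data; the other alternatives were planned. For 266 pairs of a named gene and a comparison, the alternatives gave 3926 values, of which 3645 kept their direction and side of the threshold, 211 passed newly, 50 passed no longer and 20 reversed.

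Counts of genes moved as follows, and unless stated the cause was not tested. The planned replicate block gave 0 genes for HBM against WT on each day. The added block of the paired fit took HBM against WT from 0 to 20, 214, 51 and 41 genes at days 0, 10, 15 and 21. Without batch 18 in every group it gave 55, 42, 10 and 5, without batch 19 2, 25, 18 and 130, and without batch 21 0, 5, 1 and 2, with fewer cultures. The paired models of only the 2 groups gave 0, 6, 730 and 59 on these days, with the same batch term as the paired fit but the spread estimated from 6 libraries. DESeq2 gave 2 at day 10, 1 at day 21 and 25 on average over days. There the batch block gave 36 (adjusted p from 0.047) and all 24 libraries as independent 38. Models of only the 2 groups gave 393 and 2021 in the WT and HBM steps from day 0 to day 10, where fewer libraries set the spread. The block on days 10 to 21 gave 65 and 18 for days 10 to 15 in WT and HBM and 1 for days 15 to 21 in WT. Leaving out single libraries gave 2880 to 5472 in WT and 2880 to 4413 in HBM for days 0 to 10, and 0 to 0 for each other comparison of genes.

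The lists passed 1, 7, 9 and 9 times at days 0, 10, 15 and 21. Without pairing an estimated correlation and fry, a second test of lists, gave 0 on each day. The paired fit gave 2, 9, 12 and 15, and the paired fit with an estimated correlation 0, 0, 3 and 0. Fry in the paired fit passed some lists. On the 4 days it gave adjusted p of 0.964, 0.00904, 0.00551 and 0.0172 for the osteoblast list and 0.072, 0.0359, 0.27 and 0.16 for the chondrocyte markers. Leaving out 1 library gave 0 to 4 at day 0 (0 without HBM of batch 18, 4 without HBM of batch 21), 6 to 12 at day 10 (12 without HBM of batch 21), 4 to 13 at day 15 (4 without WT of batch 21) and 6 to 13 at day 21.

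The genes with reversed values did not pass without pairing in these comparisons, but Acp5 did in the paired fit (-1.01, adjusted p = 0.00929) and Lama1 with the batch block (-0.9, 0.047). Leaving out single libraries without pairing moved them as follows. At day 0 Col1a1 ranged from -0.08 (without HBM of batch 19) to 0.42 and was -0.03 without WT of batch 21, Bmp1 from -0.07 (without WT of batch 21) to 0.07 with -0.04 without HBM of batch 19, Pcolce from -0.48 to 0.04 (without WT of batch 19), Alpl from -3.51 to 1.02 and Bglap from -0.94 to 0.11 (both without WT of batch 21), and Acp5 from -3.3 to 1.31 (without WT of batch 19). Bmp1 was also at -0.01 with the stricter filter and -0.07 in the paired fit without batch 21, and Pcolce at 0 in the paired fit without batch 19. Pcolce, without HBM of batch 18 and WT of batch 21, was at -0.08 and -0.03 at day 10 (highest 0.34), -0.09 and -0.08 at day 15 (0.29), -0.03 and -0.06 at day 21 (0.33), and -0.07 and -0.08 on average (0.22). Averaged Lama1 ranged from -2.18 to 0.37 (without WT of batch 21). Depth limits genes near 0 CPM at day 0, such as Bglap, Ibsp and Sost, whose folds from that day are uncertain.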

Other observations

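The tests of the lists in the paired fit and with the culture as a block were chosen after the result was seen; those without a block were planned.

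Some further gene lists passed in the steps between days at the preset correlation, and none of them did with an estimated correlation without a block. From day 10 to day 15, 7 of 8 osteoclast markers had higher values in WT (camera adjusted p = 0.046, and adjusted p = 0.543 with an estimated correlation, or 0.197 with the culture as a block) and in HBM (0.00138, and adjusted p = 0.349 with an estimated correlation, or 0.0454 with the culture as a block). In HBM Atp6v0d2, a subunit of the osteoclast proton pump, stood at 6.09 ± 2.72 and 21.8 ± 18.3 CPM (3 cultures per day). Factors that regulate osteoclasts had higher values in WT, 10 of 11 (0.046; adjusted p = 0.476 with an estimated correlation), with the chemokine Cxcl12 at 678 ± 214 and 1150 ± 298 CPM. Mitochondrially encoded genes had lower values, 10 of 11 in WT (0.00047; adjusted p = 0.562 with an estimated correlation) and 9 of 11 in HBM (0.00455; adjusted p = 0.636 with an estimated correlation). Chondrocyte markers, 11 of 12 (0.0045; adjusted p = 0.562 with an estimated correlation), and skeletal muscle markers, 5 of 6 (0.046; adjusted p = 0.472 with an estimated correlation), were lower in WT, and BMP and TGF-beta genes, 17 of 24, higher in HBM (0.0172; adjusted p = 0.572 with an estimated correlation). From day 15 to day 21, 20 of 22 osteoblast genes had higher values in WT (0.0244; adjusted p = 0.978 with an estimated correlation) and 8 of 11 osteoclast-regulating factors lower ones (0.0364; adjusted p = 0.793 with an estimated correlation), while 21 of 28 procollagen genes were lower in HBM (0.015; adjusted p = 0.92 with an estimated correlation). No member of these lists passed in edgeR without the block, over all genes or adjusted over the list alone, and with the culture as a block 2 osteoclast markers did from day 10 to day 15 in each genotype, adjusted over the list alone. With that block the osteoclast-regulating call from day 15 to day 21 was lost (0.0671).

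Other lists passed only with the culture as a block. From day 0 to day 10 these were 23 of 25 cell cycle genes (0.0163; adjusted p = 0.678 with an estimated correlation) and 12 of 15 immediate early genes (0.0406; adjusted p = 0.678 with an estimated correlation), lower in WT, and 5 of 6 tendon markers, higher in WT (0.0298; adjusted p = 0.395 with an estimated correlation) and HBM (0.0335; adjusted p = 0.393 with an estimated correlation). Of the Wnt genes 14 of 23 were higher in WT from day 10 to day 15 (0.0223; adjusted p = 0.391 with an estimated correlation). From day 15 to day 21 4 of 6 endothelial markers were higher in WT (0.0173; adjusted p = 0.414 with an estimated correlation) and 11 of 12 small leucine-rich proteoglycans in HBM (0.0479; adjusted p = 0.983 with an estimated correlation).

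Each of these calls made without a block was lost on leaving out a single library, and all but the WT mitochondrial call for more than 1 such library. The calls made only with the culture as a block were not tested in this way. In WT from day 10 to day 15 the osteoclast call was lost without the day 10 libraries of batches 19 and 21 (0.0803 and 0.266) or the day 15 library of batch 19 (0.967). The osteoclast-regulating call was lost without the day 10 libraries of batches 19 and 21 (0.504 and 0.0857) or the day 15 libraries of batches 18 and 21 (0.681 and 0.0641). The mitochondrial call was lost without the day 15 library of batch 18 (0.297), the chondrocyte call without the day 10 libraries of batches 19 and 21 (0.504 and 0.266) or the day 15 library of batch 18 (0.519), and the skeletal muscle call without the same libraries (0.136, 0.152 and 0.0757) or the day 15 library of batch 19 (0.269). In HBM the osteoclast call was lost without the day 10 library of batch 21 (0.0733) or the day 15 library of batch 19 (0.151). The mitochondrial call was lost without the day 10 libraries of batches 18 and 19 (0.139 and 0.971) or the day 15 libraries of batches 18 and 21 (0.586 and 0.214), and the BMP and TGF-beta call without the day 10 library of batch 21 (0.459) or the day 15 libraries of batches 18 and 19 (0.586 and 0.131). From day 15 to day 21 the WT osteoblast call was lost without the day 15 library of batch 21 (0.6) or the day 21 libraries of batches 18 and 19 (0.147 and 0.962). The osteoclast-regulating call was lost without the day 15 libraries of batches 18 and 21 (0.574 and 0.123) or the day 21 libraries of batches 19 and 21 (0.368 and 0.0773). The HBM procollagen call was lost without the day 15 libraries of batches 18 and 19 (0.402 and 0.667) or the day 21 libraries of batches 19 and 21 (0.109 and 0.295).

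Between genotypes the lists that did not pass on any of the 4 days without pairing were, with their smallest adjusted p, the small leucine-rich proteoglycans (0.611), matrix metalloproteinases and inhibitors (0.507), BMP and TGF-beta genes (0.119), Wnt genes (0.803), osteoclast-regulating factors (0.255), cell cycle genes (0.0595), immediate early and heat shock genes (0.141), mitochondrially encoded genes (0.0921) and sex-linked genes (0.382). Of the cell type markers these were those of macrophages (0.157), osteoclasts (0.1), endothelial cells (0.255), skeletal muscle (0.204), smooth muscle (0.596), Schwann cells (0.422), keratinocytes (0.154) and tendon (0.476).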
